A study of Mus musculus with 4 samples.

How the data were processed

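RNA from colony-forming cells of C57BL/6 background was amplified, labelled with biotin and hybridised to Affymetrix whole-transcript arrays, 1 array for each of 4 groups: ST-HSC mock, LT-HSC mock, ST-HSC CreER and LT-HSC CreER, per the labels. The deposited values are log2 expression per probe set, a unit read from their range of 2.21 to 14.82 and not given in the sources used here. Affymetrix Expression Console was used, per the submitters' processing notes; its version and the methods of summarisation and normalization are not given in the sources used here. The 4 columns have nearly equal distributions, so they were taken as already normalized between arrays, and they were used as deposited. Summaries of this kind compress differences near background, so differences of weakly expressed genes, and of genes under the signal floor on 1 of the 2 arrays, have an uncertain size.

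The table held 35556 probe sets. The platform annotation paired 21789 with 1 gene symbol and 1621 with several, and 12146 had no symbol here. Only probe sets with 1 symbol were named, which gave 19938 genes; 999 genes had more than 1 probe set and were represented by the one with the highest mean over the 4 arrays. Gene numbers of 21698 probe sets were found in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. No coordinates are printed, because the build behind the array annotation is not given in the sources used here.

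Each pairwise comparison is the log2 difference of 2 arrays. A gene was counted by a size rule: an absolute log2 difference of at least 1 and a level on the higher array above that array's median over probe sets with 1 symbol, called the signal floor, which lay between 8.07 and 8.13. With 1 array per group, no pairwise p-value was computed. Genes counted in both populations were set beside the overlap of independent lists. An additive model with terms for population and transduction was fitted to the 4 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over 10411 genes past the floor on at least 1 array, with Benjamini-Hochberg adjustment at 0.05. It has 1 residual degree of freedom per gene and 4.27 prior degrees of freedom. Nothing in the labels says whether cells came from separate animals, so these p-values set effects only against the spread between these arrays, not between biological replicates.

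The groups, comparisons, gene lists, rule for named genes and alternatives were fixed before the data were examined. The named genes were, for each pairwise comparison, the 10 genes furthest to each side among those meeting the size rule, leaving out gene models without a proper symbol and olfactory and vomeronasal receptors. They also were the 10 genes to each side with the largest concordant differences, ranked by the smaller of the 2 effects among genes past the floor in both comparisons, the 10 to each side whose CreER effect differs most between the populations, and always Kmt2a, Mllt1, the HoxA genes, Meis1, Zbtb16, Mecom, Kit, Cd34, Csf1r, Mpo and Itgam. Up to 4 members of each list per comparison could be named as examples, of which only some are given. Other list members are named where a count of passing members is spelled out or as further examples, chosen after their values were seen.

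There were 24 lists with 525 entries, of which 469 were measured, as 456 different genes. They covered the HoxA cluster, other MLL-fusion-associated genes, stem cell, myeloid progenitor and primary granule, neutrophil maturation, monocyte and macrophage, dendritic cell and MHC class II, mast cell and basophil, eosinophil, erythroid, megakaryocyte and platelet, B cell, T and NK cell, and fibroblast and stromal genes. They also covered cell cycle genes, p53 targets, cyclin-dependent kinase inhibitors, interferon-stimulated, ribosome biogenesis, Polycomb and MLL complex, immediate early and heat shock, hypoxia and glycolysis, and cholesterol synthesis genes, and stromal and niche interaction receptors. A list's median over members past the floor was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and is said to stand apart below the 1st or above the 99th percentile. Lists with fewer than 3 members past the floor got no median. The HoxA cluster was also described over all 10 measured members, since only 3 passed the floor.

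The alternatives for normalization were quantile normalization, cyclic loess normalization and centring each array on its median over the 19938 genes. Other alternatives were no floor, a floor at the 75th percentile, thresholds of 1.5-fold and 3-fold, and the mean of all probe sets of a gene. The last were a trend in the eBayes prior and an adjusted p of 0.1. The steps were tested on simulated data, with independent noise for each gene and variances drawn from limma's own prior. The same CreER effect was put into both populations. On the real arrays genes are not independent and CreER effects correlated weakly between the populations, so these error rates need not hold for the counts below. In simulations of the LT-HSC comparison the size rule recovered 99 of 100 genes moved by 1.5 log2 units and 9 of 100 moved by 0.75, and counted 21 of 19738 unchanged genes. In the simulation of CreER against mock, the additive fit recovered 99 of 100 genes moved by 1.5 and 60 of 100 moved by 0.75, and called 11 of 10295 unchanged genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for all else.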

Results

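Gene expression was measured in mouse colony-forming cells on 4 Affymetrix gene arrays, one for each combination of stem cell population and transduction. The starting cells were long-term and short-term haematopoietic stem cells (LT-HSC and ST-HSC), which differ in how long they sustain blood formation after transplantation. The series title describes conditional expression of MLL-ENL, a leukaemia fusion of the genes Kmt2a (MLL) and Mllt1 (ENL). Cells had been transduced with CreER, a Cre recombinase fused to the ligand-binding part of the oestrogen receptor, or with a mock control. Whether and how CreER was activated is not given in the sources used here, so a CreER minus mock difference compares the transductions and not recombined with unrecombined cells. Colonies were grown in semi-solid medium with GM-CSF, stem cell factor and the interleukins IL-6 and IL-3. The stated purpose was a first screen for genes involved in leukaemic transformation, by comparing CreER with mock in each population and LT-HSC-derived with ST-HSC-derived cells in each transduction. The array medians lay between 7.75 and 7.82 on the log2 scale. Each group held 1 array, so no pairwise difference below has a replicate check, and the number of arrays limits the precision of every value.

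The signal of Esr1, the oestrogen receptor gene, was higher on both CreER arrays than on the matching mock arrays, by 0.79 log2 units in LT-HSC-derived cells and 1.08 in ST-HSC-derived cells. Whether the Esr1 probe set detects the CreER construct is not given in the sources used here. The signals of the fusion partners differed little between CreER and mock. Kmt2a was higher by 0.14 in LT-HSC-derived and by 0.10 in ST-HSC-derived cells, and Mllt1 differed by 0.16 and -0.05. A probe set that covers sequence outside the fusion transcript would not report the fusion, so neither gene checks the labels.

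CreER-transduced LT-HSC-derived cells carried more HoxA transcripts and fewer macrophage and dendritic cell transcripts than mock-transduced LT-HSC-derived cells. Hoxa9, a homeobox gene whose high expression is a hallmark of MLL-fusion leukaemia, was higher by 1.24 with CreER, at a log2 level of 9.04 against 7.79 with mock, the latter under the signal floor. All 10 measured HoxA genes were above 0 in this comparison, with a median difference of 0.46 and a range of 0.05 to 1.24, although only 3 of the 10 passed the signal floor. Olfactory receptor genes, which are mostly silent in blood cells, drifted the same way, with a median of 0.09 and 708 of 1027 above 0. Hoxa10 was higher by 0.55, Hoxa7 by 0.50 and Hoxa6 by 0.49, and Hoxa5 was higher by 0.97 at levels of 7.28 and 6.32. Hoxa3 was higher by 0.43 and Hoxa11 by 0.22, and Hoxa2, Hoxa4 and Hoxa13 by under 0.1. Only Hoxa4, Hoxa7 and Hoxa9 passed the floor, and Hoxa7, like Hoxa9, stood under it on the mock array, at 7.75. The other HoxA genes were under it on both arrays. Among other genes tied to MLL fusions, Meis1, a partner of HOX proteins, was higher by 0.74, Lmo2 by 0.62, Zbtb16 (which encodes the zinc finger protein PLZF) by 0.60 and Myb by 0.51, whereas Zeb2 differed by -0.51 and Bcl2 by -0.37. Mecom, which encodes the transcription factor EVI1, was higher by 0.95 at levels under the floor, and by 0.65 as the mean of its 2 probe sets. The myeloperoxidase gene Mpo was higher by 0.34, the macrophage growth factor receptor gene Csf1r differed by -0.41, and Itgam and Kit differed by 0.02 and 0.06.

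The largest differences towards CreER in LT-HSC-derived cells were those of Dlk1, an imprinted gene of the Notch ligand family, at 1.69, and Fcnb, a ficolin of immature myeloid cells, at 1.65. They were followed by the histone gene H3c15 (1.37), the acute-phase protein gene Orm1 (1.30), Hspa2 (1.29), the neuropeptide gene Gal (1.18), Cd27 (1.13), the progenitor antigen gene Cd34 (1.13) and B4galt6 (1.04). The largest differences towards mock were those of the ribonuclease gene Rnase2a (-2.69, to a level of 7.91 under the floor), Fstl1 (-2.16), Slamf7 (-2.09), Chad (-1.87), the cathepsin gene Ctsk (-1.80), Cox6a2 (-1.78), Ms4a7 (-1.75), Clec4a3 (-1.70), the fibronectin gene Fn1 (-1.67) and Itgax (-1.63), which encodes the dendritic cell integrin CD11c. Slamf7, Chad, Ms4a7 and Clec4a3 also stood under the floor on the LT-HSC CreER array. H3c15, Gal and Cd27 stood under it on the LT-HSC mock array, so the size of all these differences is uncertain. Cd36 (-1.52), Mrc1 (-1.32) and Trem2 (-1.12), surface receptors of macrophages, also lay beyond the 2-fold threshold.

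In LT-HSC-derived cells the monocyte and macrophage list had a median of -0.42, with 20 of 25 members below 0 and 6 at least 2-fold lower. The dendritic cell and MHC class II list had a median of -0.61, with 12 of 13 members below 0; among them Itgax and Irf4 (-1.03) were at least 2-fold lower. The dendritic cell median was -0.21 without a filter on low values. The mast cell and basophil list had a median of -0.48, with Fcer1a, the high-affinity IgE receptor chain, at -1.30 and Gzmb at -1.17. On the other side, the myeloid progenitor and primary granule list had a median of 0.39, with 18 of 20 members above 0 and 1, Cd34, at 2-fold; other members were Prtn3 (0.89), Dmkn (0.64) and Nkg7 (0.63). The neutrophil maturation list had a median of 0.21, with 17 of 24 members above 0, including Camp (0.75) and Ltf (0.59), and none at 2-fold. The 7 members below 0 included Retnlg (-0.785) and Cxcr2 (-0.27). All 31 cell cycle genes past the floor were above 0, with a median of 0.35 and none at 2-fold. The median of the other MLL-fusion-associated genes was 0.27, with 11 of 15 members above 0 and none at 2-fold, and it was 0.11 when the floor was raised to the 75th percentile. Each of these medians, and that of the HoxA genes, lay outside the 1st to 99th percentile of random lists of matched expression.

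By the size rule, at least 2-fold and above the signal floor on the higher array, 89 of 10172 genes differed between CreER and mock in LT-HSC-derived cells. Of these, 11 were higher with CreER and 78 were lower. Of the olfactory receptor genes, 10 passed the floor and 2 met the size rule. This comparison of 2 arrays has no test, and the list medians describe these arrays only.

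**Figure D1:**
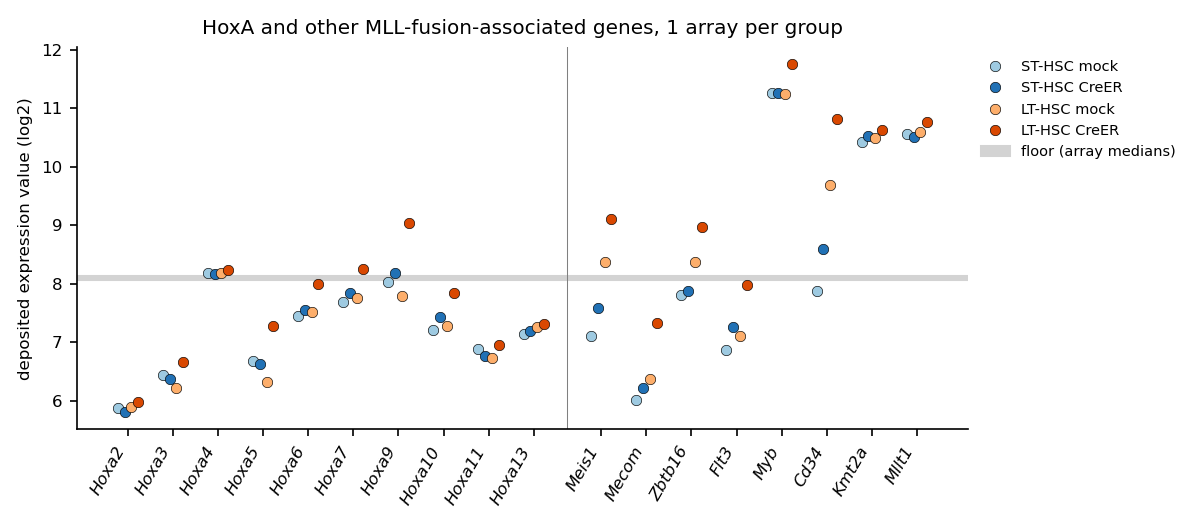
Log2 expression of the HoxA genes, other MLL-fusion-associated genes, Cd34, Kmt2a and Mllt1 on each of the 4 arrays, 1 point per array, with the range of the array floors as a grey band and no error bars because each group held 1 array. The LT-HSC CreER array has the highest Hoxa9 level, 9.04, against 7.79 on the LT-HSC mock array.

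In ST-HSC-derived cells, CreER went with higher transcripts of mature granulocytes. Olfm4, a marker of a neutrophil subset, was 4.66-fold higher with CreER, and Mmp9, the gelatinase of neutrophil granules, was higher by 2.05. Cxcr2, the chemokine receptor that draws neutrophils from the marrow, was higher by 1.64 and the neutrophil resistin-like gene Retnlg by 1.57. Genes of eosinophil granules were also higher, among them Prg2 (1.42), Epx (1.36), Prg3 (1.08) and, just past the 2-fold threshold, Ear6. Olfm4 and Mmp9 were highest on the ST-HSC CreER array. Cxcr2, Retnlg, Prg2, Epx and Prg3 instead stood lowest on the ST-HSC mock array. There Cxcr2 was at 10.46, against 12.10 on ST-HSC CreER, 12.25 on LT-HSC mock and 11.97 on LT-HSC CreER. The ST-HSC mock array enters both this difference and that of LT-HSC against ST-HSC with mock. Scrg1 (1.97, from a level under the floor), the thrombin receptor family gene F2rl2 (1.80), Slfn1 (1.65), Gzmb (1.62), Gja5 (1.55) and Slfn4 (1.51) complete the 10 largest, and the mast cell carboxypeptidase Cpa3 was higher by 1.17.

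Only 8 genes were at least 2-fold lower with CreER in ST-HSC-derived cells. They were the heat shock gene Hspa1a (-1.55), the inducible nitric oxide synthase gene Nos2 (-1.44), Fstl1 (-1.22), the coagulation factor gene F13a1 (-1.20), Lox (-1.13, to a level under the floor), Tnip3 (-1.05), Cxcl16 (-1.01) and Nrgn (-1.01). The HoxA genes did not move as a group, with a median of 0.01 and 5 of 10 members above 0. Hoxa9 was higher by 0.16, Zbtb16 by 0.06 and Meis1 by 0.49. Csf1r differed by -0.57, Mpo by -0.06, Itgam by 0.21, Kit by 0.15 and Mecom by 0.20, or by 0.10 as the mean of its probe sets.

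Of the 24 neutrophil maturation genes in ST-HSC-derived cells, 22 were above 0, with a median of 0.35 and 4 at least 2-fold higher. The eosinophil list had a median of 1.08, with 4 of 5 members at least 2-fold higher, and its median was 0.65 without a filter on low values. The mast cell and basophil list had a median of 0.35, and of 0.19 with the floor at the 75th percentile. The monocyte and macrophage list had a median of -0.30, with 24 of 26 members below 0, including Ccr2 at -0.89. The HoxA, other MLL-fusion-associated (-0.01), progenitor (-0.02) and cell cycle (0.03) medians lay within the 1st to 99th percentile of random lists, whereas the neutrophil, eosinophil, mast cell and monocyte medians lay outside it. The size rule gave 52 of 10047 genes, 44 higher and 8 lower with CreER, and 0 of the 7 olfactory receptor genes past the floor met it.

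Fstl1, a secreted glycoprotein gene, was the one gene at least 2-fold lower with CreER in both populations, against 0.03 genes for independent lists. No gene was at least 2-fold higher in both. Ranked by the smaller of the 2 effects among genes past the floor in both comparisons, the 10 largest concordant differences towards CreER were those of Olfm4, at 0.93 in LT-HSC-derived and 2.22 in ST-HSC-derived cells, Slfn4 (0.77 and 1.51), H3c15 (1.37 and 0.70), Orm1 (1.30 and 0.76), Esr1 (0.79 and 1.08), Cd34 (1.13 and 0.73), the cystatin gene Stfa3 (0.69 and 1.04), Fbxo10 (0.90 and 0.76), Foxd1 (0.70 and 0.89) and Rnase12 (0.68 and 0.69). Towards mock they were those of Fstl1, Slamf7 (-2.09 and -0.76), Bhlhe41 (-1.29 and -0.72), Arfgef3 (-1.08 and -0.82), Tnip3 (-0.96 and -1.05), the lipid-binding protein gene Fabp4 (-0.96 and -0.93), the arginase gene Arg1 (-0.97 and -0.91), Fn1 (-1.67 and -0.85), Mfge8 (-1.33 and -0.80) and Irf4 (-1.03 and -0.72). Fcer1a, Gzmb and Tph1, the serotonin synthesis enzyme of mast cells, were at least 2-fold lower with CreER in LT-HSC-derived and at least 2-fold higher in ST-HSC-derived cells. For this opposite direction, independent lists would share 0.22 genes, against the 3 found. An overlap above that of independent lists was thus not limited to genes that moved the same way.

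In the additive limma fit over all 4 arrays, 0 of 10411 genes passed a Benjamini-Hochberg adjusted p of 0.05 for CreER against mock. The smallest adjusted p from limma was 0.316, and 1048 genes had an unadjusted p under 0.05 where 520.6 are expected by chance. Adjusted over the list alone, 11 of 26 monocyte and macrophage genes were lower and 9 of 24 neutrophil maturation genes were higher with CreER in limma, against 0 of each over all genes. Among other lists that stood apart in LT-HSC-derived cells, the counts adjusted over the list alone were 0 of 3 HoxA genes, 1 higher and 1 lower of 15 other MLL-fusion-associated genes, 0 of 31 cell cycle genes, 0 of 17 mast cell and basophil genes, 1 of 20 progenitor genes, higher, and 1 of 14 dendritic cell genes, lower. They were also 1 of 3 B cell genes, lower, 0 of 6 cyclin-dependent kinase inhibitors, 0 of 16 interferon-stimulated genes and 0 of 18 immediate early and heat shock genes. The cholesterol and hypoxia lists are given further below. Across genes, which are not independent replicates, the CreER effects in the populations correlated with Pearson's r of 0.222 and Spearman's rho of 0.248, and 58.1% of genes had the same sign.

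**Figure D2:**
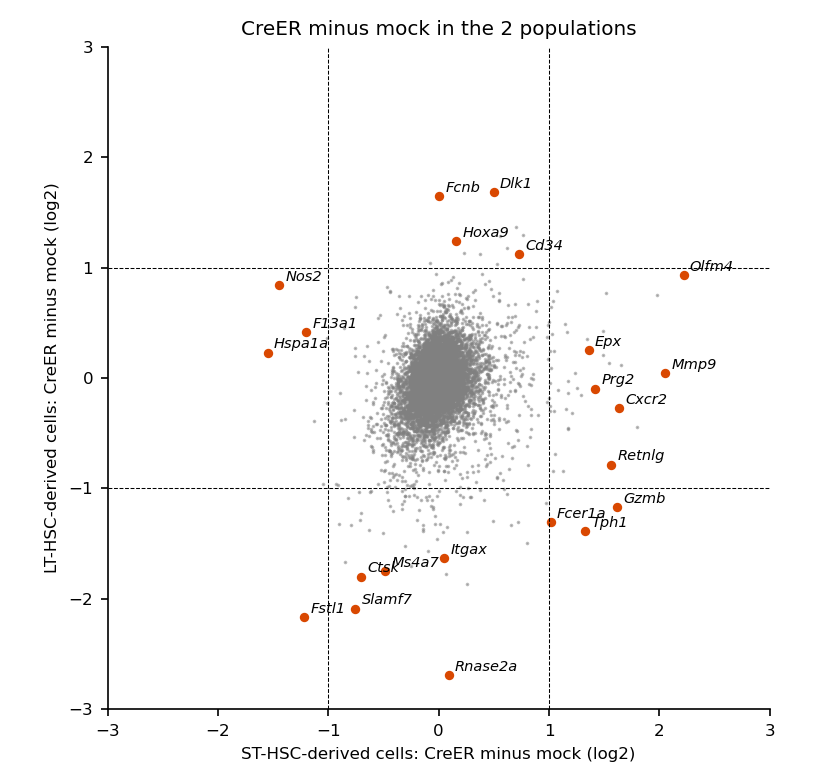
CreER minus mock on the log2 scale for each gene past the signal floor, in LT-HSC-derived cells against ST-HSC-derived cells, 1 array per group, with dashed lines at a 2-fold difference. Pearson's r across genes is 0.222; Fstl1 lies beyond -1 on both axes, and Hoxa9 is at 1.24 in LT-HSC-derived and 0.16 in ST-HSC-derived cells.

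Among mock-transduced cells, those derived from LT-HSC carried far more transcripts of mast cells and basophils than those derived from ST-HSC. Gata2, a transcription factor of stem cells and mast cells, was higher by 3.02, the histamine synthesis gene Hdc by 2.74, Cpa3 by 2.39, and the cytokine genes Il6 and Il4 by 3.68 and 2.87. Mcpt8 and Prss34, proteases of basophils, were higher by 2.05 and 1.65. The largest differences were those of the receptor gene Mrgpra6 (4.01), Rnase2a (3.92), Il6, the actin-severing protein gene Scin (3.63), the cysteine synthesis gene Cth (3.60), the glycine transporter gene Slc6a9 (3.60), Akr1c12 (3.58), Serpinb2 (3.47), the basophil receptor gene Cd200r3 (3.43) and the platelet chemokine gene Ppbp (3.29). All but Il6, Slc6a9 and Ppbp of these 10 stood under the floor on the ST-HSC mock array, with Mrgpra6 at 6.29, so the size of their differences is uncertain.

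Lower in mock-transduced LT-HSC-derived cells were Fcnb (-2.39), Nos2 (-2.29), the casein gene Csn2 (-1.90), Gal (-1.82), Orm1 (-1.80), Slco4c1 (-1.69), the B cell survival factor gene Tnfsf13b (-1.69), Tifab (-1.67), H3c15 (-1.66) and Scel (-1.54). Several of these, namely Fcnb, Orm1, Gal and H3c15, were also among the genes higher with CreER in LT-HSC-derived cells, and Rnase2a was among those lower, so the LT-HSC mock array enters both differences. Nos2, Csn2, Gal, Slco4c1, H3c15 and Scel stood under the floor on the LT-HSC mock array, so the size of their differences is uncertain. The mast cell and basophil list had a median of 2.39, with 15 of 17 members at least 2-fold higher. The eosinophil list (1.52), the megakaryocyte and platelet list (1.08, 8 of 15 at 2-fold) and the erythroid list (0.97, 3 of 6 at 2-fold) also stood above random lists, the erythroid median at 0.17 without a filter on low values. The cell cycle list was lower, at -0.23, with 30 of 31 members below 0, and the progenitor and primary granule list was lower at -0.16. The HoxA median was 0.01. Csf1r differed by -0.34, Mpo by -0.18, Itgam by -0.18 and Kit by 0.40. By the size rule 319 of 10208 genes differed, 278 higher and 41 lower in LT-HSC-derived cells.

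With CreER, LT-HSC-derived cells again carried more mast cell, basophil and megakaryocyte transcripts than ST-HSC-derived cells. Ptgs2, the inducible cyclooxygenase gene, was 9.10-fold higher, followed on the log2 scale by Il6 (3.18), Igfbp7 (2.86), Slc6a9 (2.64), Akr1c18 (2.54), the thrombin receptor gene F2r (2.37), Akr1c12 (2.37), the chemokine gene Cxcl2 (2.34), Cd200r3 (2.33) and Il4 (2.30). Il6, Akr1c12, Cd200r3 and Il4 stood under the floor on the ST-HSC CreER array. All 10 measured HoxA genes were above 0, with a median of 0.35 over all 10, above the 99th percentile of random lists, while olfactory receptor genes had a median of 0.07 with 666 of 1027 above 0. The 3 past the floor had a median of 0.41, within the 1st to 99th percentile of random lists, and none was 2-fold higher, with Hoxa9 higher by 0.85. Zbtb16 was higher by 1.11, against 0.56 with mock, and Meis1 by 1.52, against 1.27 with mock. Mecom was higher by 1.12 at levels under the floor, and by 0.65 as the mean of its 2 probe sets. Mpo was higher by 0.22 and Kit by 0.32, and Csf1r and Itgam differed by -0.19 and -0.36. The HoxA difference here shares the LT-HSC CreER array with that for CreER against mock in LT-HSC-derived cells. The HoxA shifts in these comparisons are therefore not separate observations. Without that array, the HoxA median was 0.01 for CreER against mock in ST-HSC-derived cells and 0.01 for LT-HSC against ST-HSC with mock.

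Lower in CreER-transduced LT-HSC-derived cells were the lectin gene Clec4a3 (-2.02), Csn2 (-1.91), Scrg1 (-1.87), Scel (-1.74), Slfn1 (-1.56), Ap1s2 (-1.53), Cyp4a12b (-1.52), the potassium channel gene Kcnn3 (-1.48), Mertk, a receptor for apoptotic cells (-1.44), and Fstl1 (-1.44). Clec4a3, Csn2, Scrg1, Scel and Mertk stood under the floor on the LT-HSC CreER array, so the size of their differences is uncertain. The monocyte and macrophage list had a median of -0.49, with 21 of 25 members below 0, and the neutrophil maturation list one of -0.32, with 23 of 24 below 0. The cell cycle median was 0.064, within the range of random lists, and the progenitor and primary granule median was 0.14, above it. The mast cell and basophil list had a median of 1.75, with 10 of 17 members at least 2-fold higher, although Gzmb differed by 0.02. That median was 0.78 without a filter on low values. The megakaryocyte and platelet list had a median of 0.72, with 7 of 15 members at least 2-fold higher. The size rule gave 198 of 10189 genes, 142 higher and 56 lower in LT-HSC-derived cells.

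Over both transductions, limma's additive fit called 653 of 10411 genes between LT-HSC-derived and ST-HSC-derived cells at a Benjamini-Hochberg adjusted p of 0.05. Of these, 394 were higher and 259 lower in LT-HSC-derived cells, or 60.3% higher. Centring each array on its median over the 19938 genes gave 325 higher and 339 lower, or 48.9% higher. Cyclic loess normalization gave 257 higher and 111 lower. Il6 was higher in LT-HSC-derived cells, with a log2 difference of 3.43 ± 0.142 (SE) and an adjusted p of 0.00367 in limma, and was higher in both transductions. Igfbp7, at 3.07 ± 0.130, had an adjusted p of 0.00367 in limma, and Gata2, at 2.65 ± 0.186, one of 0.00554. Slc6a9 (3.12), Akr1c12 (2.97), Cd200r3 (2.88), Ppbp (2.79), F2r (2.71), Il4 (2.59) and Akr1c18 (2.54) also passed. Csn2 (-1.90), Scel (-1.64), Gal (-1.54), Orm1 (-1.53), Tnfsf13b (-1.52), Slco4c1 (-1.44), Tifab (-1.35), Ap1s2 (-1.28), Clec4a1 (-1.23) and Il18 (-1.12) passed on the lower side. Il6 stood close to the floor on the ST-HSC arrays, at 8.10 with mock and 7.86 with CreER. Akr1c12, Cd200r3 and Il4 were under the floor on both ST-HSC arrays, and Csn2, Scel, Clec4a1 and Il18 on both LT-HSC arrays. The size of these differences is therefore uncertain, also where the standard error is small.

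Of 17 tested mast cell and basophil genes, 11 were higher in LT-HSC-derived cells in limma and none lower, and 15 were higher adjusted over the list alone. Hdc, Slc18a2, Ms4a2, Il13 and Cyp11a1 were among the 11, whereas Cpa3, Fcer1a and Gzmb did not pass over all genes. Among 15 megakaryocyte and platelet genes, 8 were higher in limma, including Pf4, Itga2b, Gp9 and Itgb3, and 9 adjusted over the list alone. Among 26 measured stem cell genes, 15 passed the floor on at least 1 array and were tested, and Mecom and Tek were among those left out. In limma 7 of the 15 were higher, namely Gata2, Thy1, Angpt1, Meis1, Msi2, Gfi1b and Cd34, and 8 adjusted over the list alone. Gata2 is also in the mast cell and basophil list, and Kit, in both lists, did not pass. Vwf and Mllt3 did not pass over all genes either. Of 15 other MLL-fusion-associated genes, Meis1, Myc, Bcl2 and Zbtb16 were higher, and 5 adjusted over the list alone. Zbtb16 had an adjusted p of 0.0437 and Meis1 one of 0.00606 in limma. Zbtb16 and Meis1 stood under the floor on both ST-HSC arrays, so the size of their differences is uncertain. Of 24 ribosome biogenesis genes 8 were higher, including Npm1, Dkc1 and Gnl3, and 17 adjusted over the list alone. Of 26 monocyte and macrophage genes 4 were lower, namely Clec4a1, Ms4a6c, Clec4n and Vcan, and 8 adjusted over the list alone.

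The LT-HSC minus ST-HSC difference was shared widely between the transductions. At least 2-fold higher with CreER and with mock were 122 genes, against 3.35 for independent lists, and 12 genes were lower in both, against 0.20. The differences correlated across genes with Pearson's r of 0.708 and Spearman's rho of 0.577. The fit has 1 residual degree of freedom per gene, which is the interaction of population and transduction. Its p-values therefore set the mean population or CreER effect against departures from additivity on these 4 arrays, not against variation between cultures or animals.

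**Figure D3:**
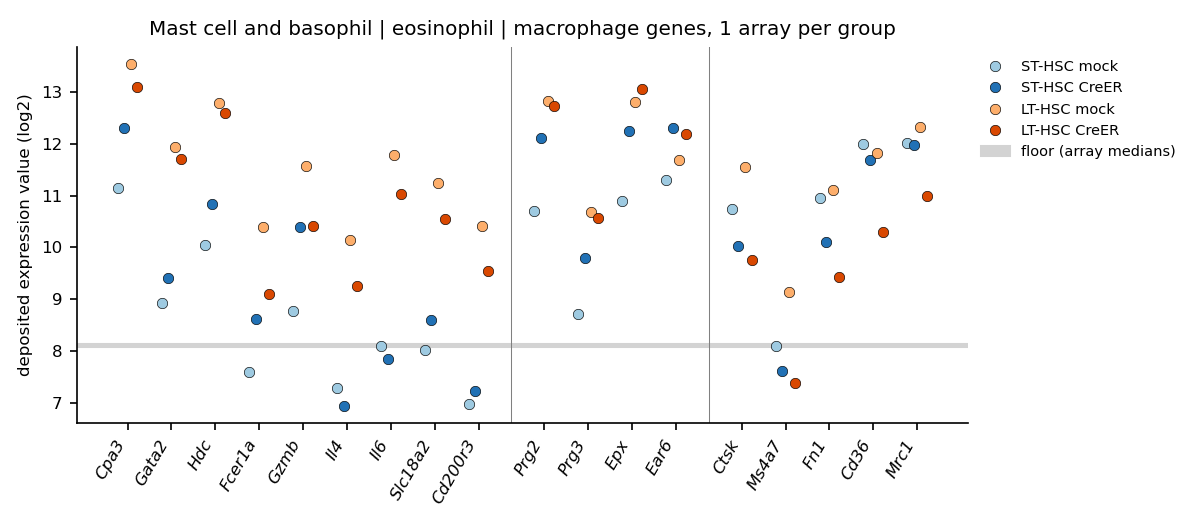
Log2 expression of mast cell and basophil, eosinophil and macrophage genes on each of the 4 arrays, 1 point per array, with the range of the array floors as a grey band and no error bars because each group held 1 array. Il6 lies at 11.78 and 11.04 on the LT-HSC arrays against 8.10 and 7.86 on the ST-HSC arrays, and Ctsk is lowest on the LT-HSC CreER array at 9.76.

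Some lists differed in only part of the comparisons. The dendritic cell and MHC class II median for LT-HSC against ST-HSC was -0.33 with CreER and 0.33 with mock, but these signs turned to 0.069 and -0.037 without a filter on low values, and the mock median was -0.19 with the floor at the 75th percentile. Interferon-stimulated genes had a median of -0.36 for CreER against mock in LT-HSC-derived cells, with Irf7 at -0.79 and Usp18 at -0.72, and of 0.02 in ST-HSC-derived cells; the LT-HSC value was -0.06 without a filter on low values. The stem cell median was 0.06 and 0.02 for CreER against mock in the 2 populations. Polycomb and MLL complex genes had medians between -0.03 and 0.07 in the 4 comparisons, and p53 target genes between -0.16 and 0.09, all within the range of random lists.

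Cyclin-dependent kinase inhibitors had medians of 0.22 and 0.26 for CreER against mock in LT-HSC-derived and ST-HSC-derived cells, above random lists in both, with Cdkn3 at 0.24 and 0.28. Fibroblast and stromal genes had medians between -0.02 and 0.24, within the range of random lists. Stromal and niche interaction receptors stood apart only for LT-HSC against ST-HSC with mock, at 0.17. Of the B cell genes 3 passed the floor, with a median of -0.53 for CreER against mock in LT-HSC-derived cells, which was 0.080 without a filter on low values. Of the T and NK cell genes only Thy1 and Nkg7 passed the floor, too few for a median. Over the 4 comparisons 90 list medians were computed; 33 lay above the 99th and 16 below the 1st percentile of random lists, where 1.8 would be expected by chance. Genes within a list are not independent, and 11 genes belong to more than 1 list.

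**Figure D4:**
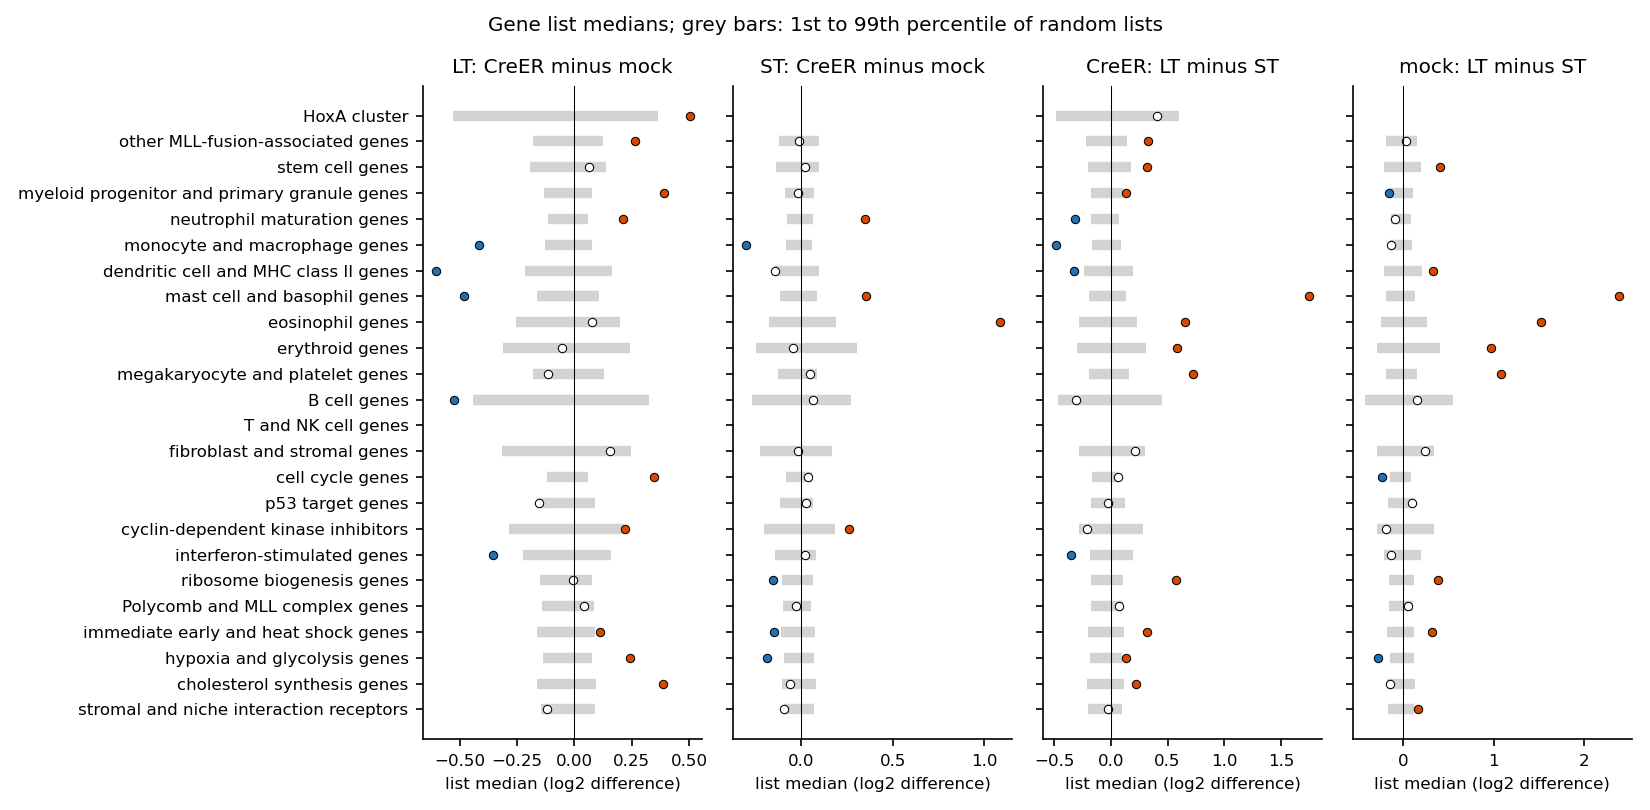
Median log2 difference of each gene list in the 4 pairwise comparisons, over members past the signal floor, with grey bars from the 1st to the 99th percentile of random lists and filled points where the median lies outside them. The mast cell and basophil list is highest, at 2.39 for LT-HSC against ST-HSC with mock and 1.75 with CreER.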

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

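The tests of array scaling were set before their results were seen; those of cell composition and of exchanged labels were chosen only after the result was seen. Several list medians and genes moved in opposite directions in the groups compared, and none of these differences between groups was tested, since each rests on 4 single arrays.

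The list medians of HoxA and other MLL-fusion-associated genes were above those of random lists for CreER against mock in LT-HSC-derived cells, with 1 of 3 and 0 of 15 members past the floor at least 2-fold higher. Both lists stayed above random lists under 3 other normalizations of the deposited values. The lowest median was 0.37 for the 10 HoxA genes and 0.24 for the other list. The columns were nearly equal before these steps, so this test could shift the medians little and cannot decide on scaling before deposition. A lower share of macrophages and dendritic cells alone would raise the other cell types alike. The mast cell and basophil median differed from the progenitor median by -0.87 (95% interval over genes, which are not independent, -1.25 to -0.58). However, mast cell and basophil genes were themselves lower, with a median of -0.48. The test therefore cannot exclude a joint fall in the shares of macrophages, dendritic cells and mast cells. A larger share of immature progenitors remains open, because progenitor and primary granule genes (0.39) and cell cycle genes (0.35) were higher than on the LT-HSC mock array, but that array was itself low for both lists, and against the ST-HSC CreER array the medians were 0.14 and 0.064. An effect of MLL-ENL itself may add to this and remains a hypothesis, as culture, batch and group cannot be told apart with 1 array each and activation of CreER is not given in the sources used here.

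Mast cell and basophil genes were higher in LT-HSC-derived than in ST-HSC-derived cells in both transductions. Under the other normalizations of the deposited values the lowest median was 1.68 (highest 2.41). The columns were nearly equal beforehand, so this test cannot decide on scaling before deposition. LT-HSC and ST-HSC labels exchanged on one pair of arrays are argued against by a correlation of 0.71 across genes between the transductions (95% interval over genes 0.69 to 0.73). A larger share of mast cells or basophils remains open, because the share of list members at least 2-fold higher, 58.8% with CreER and 88.2% with mock, restates the pattern and decides nothing. Of the strongly expressed list members, Cpa3, Mcpt8, Hdc and Prss34 stood at log2 levels of 13.09, 13.20, 12.59 and 12.57 on the LT-HSC CreER array and at 12.31, 11.49, 10.84 and 10.75 on the ST-HSC CreER array, and no sort of the colony cells is described in the labels. Whether the starting population or the culture gave rise to such cells cannot be told apart, because each population was grown once per transduction.

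Between the populations, the CreER minus mock median of hypoxia and glycolysis genes was 0.24 in LT-HSC-derived and -0.19 in ST-HSC-derived cells. That of immediate early and heat shock genes was 0.11 and -0.15, and that of mast cell and basophil genes -0.48 and 0.35. Between the transductions, the LT-HSC minus ST-HSC median of dendritic cell and MHC class II genes was -0.33 with CreER and 0.33 with mock. The corresponding medians were 0.13 and -0.28 for hypoxia and glycolysis genes and 0.14 and -0.16 for myeloid progenitor and primary granule genes. Fcer1a differed between CreER and mock by -1.30 in LT-HSC-derived and 1.01 in ST-HSC-derived cells, Gzmb by -1.17 and 1.62, and Tph1 by -1.39 and 1.32. Among probe sets with no gene symbol here, which no comparison of genes used, 189 were at least 2-fold lower and 20 higher in LT-HSC-derived than in ST-HSC-derived cells with CreER, against 73 lower and 55 higher with mock and, among named genes with CreER, 56 lower and 142 higher.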

How the results depend on the processing

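All alternatives were planned, and counts followed the thresholds by construction. With the floor at the 75th percentile, fewer genes could pass: 53 for CreER versus mock in LT-HSC-derived cells, 93 for LT-HSC versus ST-HSC with CreER, 169 for LT-HSC versus ST-HSC with mock, and 186 in limma's additive fit of the populations. At 1.5-fold the counts were 417 for CreER versus mock in LT-HSC-derived cells, 200 for CreER versus mock in ST-HSC-derived cells, 697 and 825 for the populations with CreER and with mock, and 30 genes shared by both CreER effects. At 3-fold, in the same order, they were 12, 7, 67, 143 and 0. The population fit called 368 genes after cyclic loess, for which the cause was not tested, and 1401 at an adjusted p of 0.1. The CreER coefficient called 0 genes under every alternative, the smallest limma adjusted p ranging from 0.179 to 0.420. Of the list medians, 498 alternative values stayed close, 19 moved and 4 reversed. Close means a shift smaller than a robust spread of single genes, 0.14 to 0.24 by comparison, so a small median can shrink much and still count as close. Whether a list still stood apart was rechecked only for the HoxA and other MLL-fusion-associated lists under the other normalizations. The B cell median for CreER against mock in LT-HSC-derived cells became 0.080 without a filter on low values. The dendritic cell and MHC class II median for LT-HSC against ST-HSC became 0.069 with CreER and -0.037 with mock without a filter, and -0.19 with mock at the 75th percentile. The cause of these reversals was not tested. Of the named genes' alternative values 1909 stayed close and 3 moved, all of them Mecom, whose 2 probe sets differ. The LT-HSC effects of Hoxa2, Hoxa3, Hoxa5, Hoxa6, Hoxa10, Hoxa11, Hoxa13 and Mecom rest on levels under the floor, where signal over background is small. Hoxa7 and Hoxa9 stood under the floor on the LT-HSC mock array only.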

Other observations

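Cholesterol synthesis genes are a group not described above. In LT-HSC-derived cells all 17 had a CreER minus mock difference above 0, with a median of 0.39 and none at 2-fold, including the sterol dehydrogenase gene Nsdhl at 0.70, Hsd17b7 at 0.61 and Lss at 0.59; in ST-HSC-derived cells the median was -0.06. Of 20 hypoxia and glycolysis genes 17 were above 0 in LT-HSC-derived cells and none was at 2-fold, with the mitophagy gene Bnip3 at 0.83, Pdk1 at 0.75 and Pfkl at 0.58. These 3 genes stood at -0.47, -0.36 and -0.37 in ST-HSC-derived cells. In limma's additive fit 0 of 17 cholesterol and 0 of 21 hypoxia and glycolysis genes passed for CreER against mock or for LT-HSC against ST-HSC, also adjusted over the list alone. Ribosome biogenesis genes had a median of 0.57 for LT-HSC against ST-HSC with CreER and 0.38 with mock, and 65 ribosomal protein genes had medians of 0.21 and 0.13. For CreER against mock the ribosome biogenesis median was -0.01 in LT-HSC-derived and -0.15 in ST-HSC-derived cells. Whether the CreER effects on these lists differed between the populations was not tested.

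The immediate early and heat shock list had a median of 0.32 for LT-HSC against ST-HSC with CreER, with 4 of 18 members at least 2-fold higher. With mock the median was also 0.32, with 3 members at least 2-fold higher, 1 lower and 5 below 0. Fosb differed by 1.93 with CreER and 1.32 with mock, Egr1 by 1.37 and 1.02 and Dusp1 by 1.15 and 0.80, and limma's additive fit called 6 of 18 members higher. Hspa1a stood apart from them on the ST-HSC mock array alone, so that it differed by -1.46 with mock and 0.32 with CreER. The genes whose CreER effect was furthest above that of the other population in LT-HSC-derived cells were Nos2 (2.29), Hspa1a (1.78), Fcnb (1.65), F13a1 (1.61), Mid1 (1.49), Ak4 (1.40), Nrgn (1.37), Scd1 (1.31), Bnip3 (1.30) and Selenbp1 (1.23). Furthest below were Gzmb (-2.78), Rnase2a (-2.78), Tph1 (-2.71), Retnlg (-2.35), Fcer1a (-2.32), F2rl2 (-2.24), Chad (-2.13), Ctse (-2.10), Ch25h (-2.03) and Mmp9 (-2.01).

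The erythroid list differed little with CreER, with medians of -0.06 in LT-HSC-derived and -0.05 in ST-HSC-derived cells, and the megakaryocyte and platelet list had medians of -0.12 and 0.05. Xist, the X-inactivation transcript, and the Y-linked genes Eif2s3y, Kdm5d and Uty were all above the signal floor on all 4 arrays. Xist stood at 11.47 on both mock arrays, 10.70 on the ST-HSC CreER array and 10.94 on the LT-HSC CreER array. Eif2s3y stood at 10.45 on the ST-HSC mock array, 10.48 on the LT-HSC mock array, 10.85 on the ST-HSC CreER array and 10.28 on the LT-HSC CreER array. Donor sex and pooling are not given in the sources used here, so whether the mix of donors was the same on the CreER and mock arrays is unknown. Uty ranged from 9.56 to 9.91 and Kdm5d from 9.13 to 9.23 over the 4 arrays.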
